A study of Gallus gallus with 15 samples.

How the data were processed

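Liver RNA of broiler breeder hens was measured by RNA sequencing in 15 libraries, 5 from hens without metformin and 10 from hens fed metformin at a dose of 75 mg/kg of body weight. Per the labels' protocols, hens received the diets for 40 weeks, from 25 to 65 weeks of age, with 45 hens per treatment group, and libraries were made from 200 ng of total RNA with a stranded mRNA kit. The labels do not state that each library came from a separate hen, so p-values measure the spread between these samples.

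The deposited table holds raw read counts per gene that the authors made before deposit. FastQC 0.12.0, Trim Galore 0.6.4, STAR 2.7.11b and HTSeq 0.12.3 are named in the submitters' processing notes, as are the chicken genome builds GRCg6a and galGal6, which are names of a single assembly. The strand setting of the counting is not given in the sources used here. The table has 24154 gene rows and 5 closing rows of reads outside the gene counts. Of the gene names, 21 had been turned into dates and were kept as they stood. By symbol, 18461 gene rows matched a RefSeq gene table of another assembly, GRCg7b, which was used only for names, gene spans and neighbours, so no coordinates are given.

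The closing rows stayed out of library sizes and tests. Reads in no gene made up 14.6% to 55.1% of the reads in the table per library, reads with more than one place 2.29% to 12.0%, and reads in more than one gene 0.411% to 0.870%. Gene totals ran from 8023809 to 41041301 reads per library. Wilson 95% intervals of the share in no gene reached at most 0.0219 percentage points to either side, and they cover counting error only. No library pair agreed within sampling noise over the 2000 most abundant genes, where the smallest chi-square per degree of freedom was 90.6.

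Metformin was compared with control by edgeR 4.0.16 in R 4.3.3 with its quasi-likelihood test, TMM factors, the default expression filter and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. All adjusted p-values of genes come from edgeR unless another tool is named. CPM values are counts scaled to the usual CPM unit by the TMM-scaled library size, given as mean ± SD. In this fit 14432 genes were tested. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 44 of 46 lists that had at least 5 tested members. Camera with an estimated correlation and fry were run beside it.

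The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 called genes with the largest log2 fold change in each direction among those with a symbol and an average log2 CPM of at least 0. It took from each list up to 4 called members with the smallest p, or the 1 with the smallest p where none was called, and 20 genes in any case. It gave 186 tested genes, and each alternative was run on those of them to which it gave a value. Genes quoted for a list are those with the smallest p, except that some genes are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

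The libraries fell into 3 sets by the share of reads in no gene, taking a gap of over 5 percentage points between neighbours as a border. This border was chosen after seeing the data. The middle set held the 5 control libraries and metformin 1, 3 and 4, the low set metformin 2 and 5, and the high set metformin 6 to 10. A fit with the set as a covariate, called set-adjusted, and a fit of the 8 libraries of the middle set were therefore added, the first also with each library left out in turn. In the set-adjusted fit the metformin term rests on the 5 controls against metformin 1, 3 and 4.

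The alternative settings were DESeq2 1.42.0, RLE and upper quartile factors, no filter, a filter of CPM at least 1 in at least 5 libraries, the replicate number as a block, robust dispersion, limma voom with sample quality weights, 1 surrogate variable from sva 3.50.0, and each library left out in turn. The calculations were tested on simulated counts drawn from the real gene means, library sizes and dispersions with 200 changed genes. With no set differences over 14160 genes, the test of all libraries recovered 65% of genes changed 2-fold and 95% of those changed 4-fold, with 4 unchanged genes called. With the real set differences and 14092 genes it recovered 60% and 79%, and it called 1865 unchanged genes. The set-adjusted fit of the same simulated counts recovered 41% and 79%, with 9 unchanged genes called. The same set means and dispersions, without any metformin effect, were drawn 20 times to give no-effect values for the counts of calls. Any metformin effect in the low or the high set is part of their set means in these simulations. Each gene was drawn independently, without variation that a library shares across genes.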

Results

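Gene expression was measured in the liver of broiler breeder hens, the parent stock of meat chickens, at 65 weeks of age. Metformin is an oral drug that lowers blood glucose in mammals. The comparison asked which liver transcripts differed between 10 libraries from hens given metformin and 5 libraries from hens without it. Reads assigned to genes numbered 21435678 to 26494240 in control libraries and 8023809 to 41041301 in metformin libraries.

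The metformin libraries were not of one kind. Reads in no gene made up 27.8% to 36.3% in the 5 controls, 37.0% to 43.5% in metformin 1, 3 and 4, 14.6% to 17.5% in metformin 2 and 5, and 51.5% to 55.1% in metformin 6 to 10. The first principal component of log2 CPM held 52.8% of the variance. Rank correlations between libraries were at least 0.92 within a set and at most 0.898 between sets. Ribosomal RNA genes took 10.2% to 20.2% of gene counts in controls, 12.6% to 34.4% in metformin 1, 3 and 4, 1.09% to 1.35% in metformin 2 and 5, and 2.69% to 11.3% in metformin 6 to 10. No control library lay in the low or the high set, so in those sets metformin and set cannot be told apart. Within the middle set metformin 1, 3 and 4 each had a higher share in no gene than every control. Metformin and this share are therefore not separated there either.

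**Figure D1:**
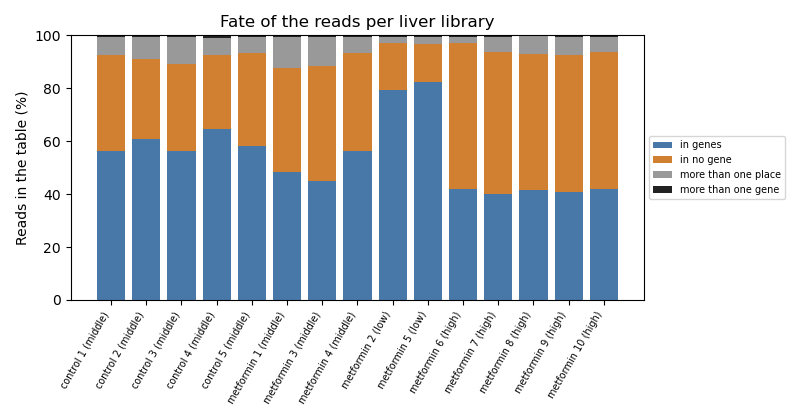
Share of the reads in the table (y axis, percent) that were counted in genes, in no gene, at more than one place or in more than one gene, for each of the 15 libraries (x axis, with the library set). The 5 libraries of the high set have over 51.4% of reads in no gene, and the 2 of the low set at most 17.5%.

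Glucose-6-phosphatase, G6PC, which releases glucose from the hepatocyte, fell from 2357 ± 682 CPM in controls (SD, n = 5) to 527 ± 244 CPM with metformin (SD, n = 10). Its log2 fold change was -2.16 ± 0.30 (SE, adjusted p = 0.0113), and it lay below all controls in 10 of 10 metformin libraries. NFKBIA, an inhibitor of NF-kB, fell from 147 ± 64.4 to 30.5 ± 11.9 CPM, by 2.27 on the log2 scale (adjusted p = 0.0113, 10 of 10 libraries). ANGPTL4, an inhibitor of lipoprotein lipase, rose from 104 ± 48.2 to 560 ± 277 CPM, a log2 fold change of 2.42 (adjusted p = 0.0180, 9 of 10 libraries above all controls). PPP1R3B, which brings protein phosphatase to glycogen, rose from 125 ± 42.7 to 338 ± 90.5 CPM, a log2 fold change of 1.44 (adjusted p = 0.0180, 10 of 10 libraries).

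Over all 15 libraries, 1805 genes were higher and 827 lower with metformin. Of the 56 ways to take 5 libraries of the middle set as controls against the other 10, the real one included, 10 gave at least as many higher and 9 at least as many lower. Simulated counts with the set differences and no metformin effect gave 1080 to 1350 higher and 275 to 407 lower. With the library set as a covariate 4 were higher and 1 lower, and 1678 genes had an unadjusted p under 0.05. The simulations without a metformin effect gave 0 to 1 calls in that fit. In the 8 libraries of the middle set 0 were higher and 1 lower with edgeR, and 1390 had an unadjusted p under 0.05. The call counts also rested on single controls: 540 higher and 336 lower without control 1, 2 and 4 without control 2, 233 and 182 without control 3, 16 and 39 without control 4, and 0 and 0 without control 5. These are counts past the threshold. The log2 fold changes of 8 called named genes moved by over 1.5 times without 1 library, and those of the others compared by less. With the replicate number as a block, or with 1 surrogate variable, 0 genes were called in either direction by edgeR.

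Set-adjusted values of the genes above were -1.44 for G6PC (adjusted p = 0.0644), -1.91 for NFKBIA (adjusted p = 0.0817), 2.74 for ANGPTL4 (adjusted p = 0.0644) and 1.42 for PPP1R3B (adjusted p = 0.0817). None of these passed the threshold with all libraries kept. With control 1 left out all 4 did, at -1.43 (adjusted p = 0.0143), -1.86 (adjusted p = 0.0276), 2.6 (adjusted p = 0.0173) and 1.58 (adjusted p = 0.0103). G6PC and NFKBIA also passed without control 4, and ANGPTL4 without metformin 3 or 10. Without the library that moved each value most, none passed. G6PC had -1.31 and NFKBIA -1.67 without control 2 (adjusted p = 0.163 for each). ANGPTL4 had 2.29 without metformin 1 (adjusted p = 0.180), and PPP1R3B 1.66 without metformin 3 (adjusted p = 0.0980). Of the 1805 genes called higher, 1359 (75.3%) had the same sign in the set-adjusted fit, and of the 827 called lower, 827 (100%) did. In 20 simulations with the differences between sets and no metformin effect, these shares were 69.1% to 71.9% and 100%. The median log2 fold change of the genes called higher was 1.64 over all libraries and 0.31 set-adjusted, and that of the genes called lower was -0.95 and -0.44. In 94 genes all metformin libraries lay above all controls and in 152 genes below. Libraries without any set differences would give 4.81 genes per direction by chance, and the simulations gave 37 to 62 above and 41 to 71 below. The simulations drew each gene independently, without variation that a library shares across genes. Counts and shares outside their ranges therefore do not by themselves speak for a metformin effect.

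**Figure D2:**
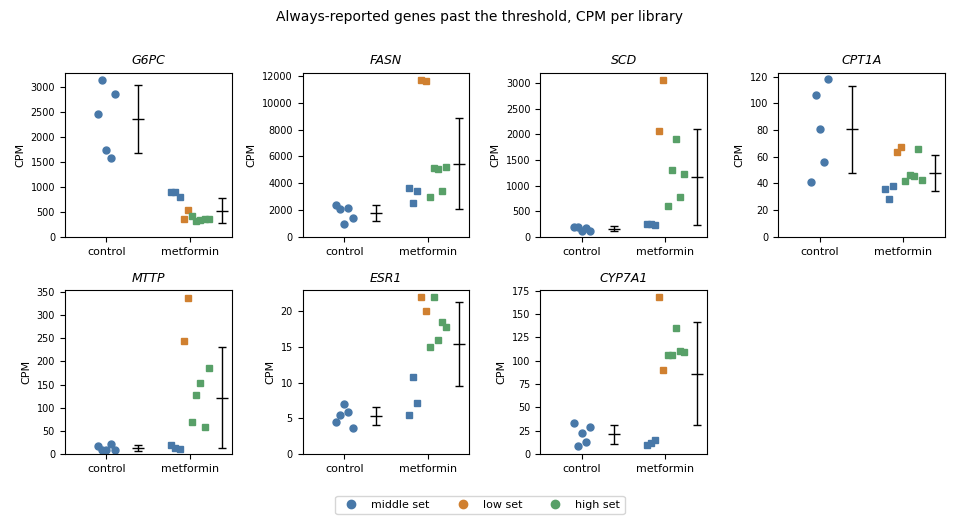
CPM (y axis) of 7 genes that were to be reported in any case and passed the threshold, with 1 point per library, colour for the library set, and mean and SD beside each group. G6PC lies below the controls in each metformin library, whereas MTTP and CYP7A1 in metformin 1, 3 and 4 lie among the controls.

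Among 26 tested genes of sterol synthesis and uptake, 10 rose and 1 fell, and 11 and 1 adjusted over the list alone. The list passed the camera test upward (adjusted p = 0.00245; adjusted p = 0.684 with an estimated correlation), and set-adjusted too (adjusted p = 3.39e-09; adjusted p = 0.556 with an estimated correlation). DHCR7 had a log2 fold change of 1.43 over all libraries and 0.96 set-adjusted, and NSDHL, another enzyme of sterol synthesis, had 1.69 and 0.94. SCARB1 was the member that fell (-0.85, and -0.79 set-adjusted).

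Among 16 glycogen genes 5 rose and 0 fell, and 6 and 0 adjusted over the list alone. The list passed upward (adjusted p = 0.0111; adjusted p = 0.684 with an estimated correlation), and set-adjusted (adjusted p = 0.000244; adjusted p = 0.123 with an estimated correlation). Beside PPP1R3B, PPP1R3C had a log2 fold change of 3.75 over all libraries and 1.22 set-adjusted (0.75 without metformin 4). GYG1, which primes glycogen, had 0.71 and 0.44. Of 22 gluconeogenesis genes 4 rose and 3 fell (4 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.633). LDHB fell with G6PC (-1.85, and -1.69 set-adjusted), and PCK2 (2.46) and PC (1.77) rose, with set-adjusted values of 0.70 and 0.42. PCK1 was near the floor, at 1.21 ± 0.906 CPM in controls and 1.25 ± 1.36 CPM with metformin. FBP1 had a log2 fold change of -0.34 (adjusted p = 0.212) and -0.56 set-adjusted. Of 26 glycolysis genes 3 rose and 1 fell, the same adjusted over the list alone (adjusted p of the list = 0.846). PGK1 rose (1.94) but had -0.17 set-adjusted, which turned to 0.13 without control 4.

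Of 32 genes of fatty acid and triglyceride synthesis 8 rose and 3 fell, and 10 and 3 adjusted over the list alone. The list did not pass over all libraries (adjusted p = 0.114), and set-adjusted it passed upward (median 0.24, adjusted p = 0.0177; adjusted p = 0.556 with an estimated correlation). ACACB fell by 3.92 on the log2 scale, SCD and GPAM rose by 2.84 and 1.74, and their set-adjusted values were -3.14, 0.57 and 1.92. FASN, fatty acid synthase, went from 1788 ± 586 to 5471 ± 3393 CPM and lay above all controls in 10 of 10 metformin libraries, with a log2 fold change of 1.61 (adjusted p = 0.0283) and 0.85 set-adjusted (adjusted p = 0.302). SREBF1 had 0.64 (adjusted p = 0.0550) and ACACA 0.72 (adjusted p = 0.0537), with 1.01 and 0.49 set-adjusted. Of 31 genes of fatty acid oxidation and ketogenesis 3 rose and 5 fell, and 9 and 8 adjusted over the list alone (adjusted p of the list = 0.633). Set-adjusted, 23 of the 31 were lower and the list passed downward (median -0.36, adjusted p = 0.00163; adjusted p = 0.556 with an estimated correlation), as did the 29 hepatocyte markers, with a median of -0.36 too. Beside ANGPTL4, CYP4B7 fell by 2.09 on the log2 scale and had -1.63 set-adjusted. CPT1A, which admits fatty acids to mitochondria, had -0.76 (adjusted p = 0.0460) and -1.23 set-adjusted. PPARA had 1.16 (adjusted p = 0.0529) and -0.20 set-adjusted.

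Of 34 genes of respiratory complex I 0 rose and 8 fell (1 and 16 adjusted over the list alone), and of 35 of complexes II to V 0 rose and 8 fell (0 and 15). Both passed downward (adjusted p = 2.32e-07 and 8.14e-07), each with an adjusted p = 0.684 with an estimated correlation. NDUFA8 had -0.89 and COX6C -1.04, with -0.62 and -0.59 set-adjusted. The median log2 fold changes of the lists were -0.74 and -0.80 over all libraries and -0.20 and -0.13 set-adjusted (adjusted p = 0.0175 and 0.0177; adjusted p = 0.785 for each with an estimated correlation). Of 81 cytosolic ribosomal protein genes 40 fell and 3 rose (70 and 5 adjusted over the list alone), which passed downward (adjusted p = 5.47e-19; adjusted p = 0.684 with an estimated correlation). Their median log2 fold change was -1.08 over all libraries and -0.23 set-adjusted. Of 31 proteasome genes 5 fell and 0 rose (6 and 0 adjusted over the list alone), with PSMB7 at -0.70 (-0.41 set-adjusted), and passed downward with adjusted p = 0.0111 and adjusted p = 0.684 with an estimated correlation. Of 26 genes of the citrate cycle and pyruvate dehydrogenase 10 rose and 1 fell (12 and 1 adjusted over the list alone), upward with adjusted p = 0.0103 and adjusted p = 0.684 with an estimated correlation. DLAT rose by 3.51 and MPC1, the mitochondrial pyruvate carrier, fell by 1.16, with 0.67 and -1.32 set-adjusted. The set-adjusted median of this list was 0.01 (adjusted p = 0.417).

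Of 44 cell cycle genes 6 rose and 0 fell (3 and 0 adjusted over the list alone), upward with adjusted p = 0.00149 and adjusted p = 0.684 with an estimated correlation. SMC2 had 2.84 and BUB1 2.22, with 1.35 and 1.97 set-adjusted. The median of the list was 0.93 over all libraries and 0.33 set-adjusted (adjusted p = 0.0293; adjusted p = 0.785 with an estimated correlation). Of 16 markers of heterophils and thrombocytes 2 fell and 0 rose, the same adjusted over the list alone (adjusted p of the list = 0.0185; adjusted p = 0.684 with an estimated correlation), with AvBD6 at -2.66 (-2.58 set-adjusted). In all 9 lists passed, 4 upward and 5 downward, 0 passed with an estimated correlation, and 12 passed with fry, which tests the members without comparing them with other genes. With the set as a covariate 19 lists passed at the preset correlation, 8 of the 9 in the same direction, 0 passed with an estimated correlation (smallest adjusted p = 0.123), and 1 passed with fry.

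The other lists did not pass over all libraries. Of 30 genes of AMPK and mTOR signalling 5 rose and 1 fell (6 and 2 adjusted over the list alone), with TSC1 at 1.08 (0.77 set-adjusted) and ULK1 at 1.21 (0.98 set-adjusted), adjusted p of the list = 0.387. The catalytic subunits PRKAA1 and PRKAA2 had 1.14 (adjusted p = 0.0988) and 0.37 (adjusted p = 0.601), with -0.70 and -0.11 set-adjusted. Of 24 insulin and IGF genes 6 rose and 1 fell, the same adjusted over the list alone (adjusted p of the list = 0.194). IGFBP1, a hepatic protein that binds insulin-like growth factors, fell by 1.6 on the log2 scale and had -2.27 set-adjusted (adjusted p = 0.0947), and PIK3CA rose by 2.39 and had 0.46 set-adjusted. IGF1 was below the filter, with at most 9 reads in a library. Of 7 genes of metformin and cation transport 2 rose and 1 fell (3 and 1 adjusted over the list alone), with SLC22A4 at 3.49 (1.22 set-adjusted), adjusted p of the list = 0.973. SLC19A2 rose from 1 read in controls to 315 with metformin, of which metformin 1, 3 and 4 held 0, a ratio of 186 at equal library size (exact binomial 95% interval 33.2 to 7386, counting error only).

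Of 44 acute phase and innate immune genes 1 rose and 6 fell (1 and 5 adjusted over the list alone), with SOCS1 at -1.48 (-1.19 set-adjusted) beside NFKBIA (adjusted p of the list = 0.633). Of 38 interferon response genes 3 rose and 5 fell (3 and 7), with HELZ2 at 2.92 (0.69 set-adjusted) and IFI6 at -2.73 (-2.20 set-adjusted, and without control 4 -1.21 and -0.68) and a list p of 0.211. Of 36 xenobiotic metabolism genes 4 rose and 5 fell (4 and 5), with CYP2AC1 at -1.67 (-1.21 set-adjusted) and CYP2C23b at -2.67 (-1.89 set-adjusted) and a list p of 0.387. Of 33 antioxidant genes 0 rose and 4 fell (0 and 4), with TALDO1 at -0.68 (-0.60 set-adjusted) and a list p of 0.226. Of 31 immediate early genes 4 rose and 5 fell (5 and 6), with ZFP36L2 at 2.88 (0.18 set-adjusted) and RHOB at -1.58 (-2.03 set-adjusted) and a list p of 0.419. The set-adjusted value of RHOB was -3.21 without metformin 1. Of 25 circadian clock genes 3 rose and 0 fell (5 and 0), with BHLHE41 at 1.17 (1.6 set-adjusted) and a list p of 0.114. Here and in the next 2 paragraphs the values in parentheses after the calls are the calls adjusted over the list alone, and the list p is the adjusted p of the list.

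Of 34 ATF4 target genes 4 rose and 4 fell (6 and 6), with NARS at 1.81 (0.98 set-adjusted) and PSPH at -1.19 (-0.70 set-adjusted) and a list p of 0.921. Of 33 genes of endoplasmic reticulum chaperones and the unfolded protein response 7 rose and 1 fell (8 and 3), with EDEM1 at 4.64 (-0.51 set-adjusted) and CRELD2 at 1.22 (0.15 set-adjusted) and a list p of 0.194. Of 28 heat shock genes 6 rose and 0 fell (6 and 0), with HSF1 at 1.34 (0.83 set-adjusted) and a list p of 0.785. Of 24 bile acid genes 3 rose and 2 fell (4 and 2), with NR5A2 at 1.36 (0.43 set-adjusted) and NR0B2 at -0.98 (-0.57 set-adjusted) and a list p of 0.846. Of 31 genes of methionine, choline and one-carbon metabolism 4 rose and 1 fell (3 and 1), with CHDH at 1.40 (1.02 set-adjusted) and a list p of 0.846. The set-adjusted value of CHDH was 0.49 without metformin 1. Of 20 purine genes 3 rose and 1 fell (4 and 1), with ATIC at -1.10 (-1.07 set-adjusted) and a list p of 0.846. Of 41 amino acid catabolism genes 5 rose and 0 fell (3 and 0), with GLUD1 at 2.92 (0.16 set-adjusted) and a list p of 0.846. Of 25 senescence and p53 genes 2 rose and 2 fell (2 and 2), with TP53INP1 at 1.46 (1.09 set-adjusted) and a list p of 0.846. Of 15 genes of the thyroid and glucocorticoid axis 2 rose and 1 fell (4 and 2), with DIO3 at -4.77 (-4.42 set-adjusted) and THRB at 1.09 (0.62 set-adjusted) and a list p of 0.532. Of 22 iron and haem genes 4 rose and 3 fell (6 and 4), with UROD at -0.72 (-0.45 set-adjusted) and TFRC at 3.37 (0.43 set-adjusted) and a list p of 0.927. The set-adjusted value of TFRC was 0.96 without control 3 and changed sign without metformin 1. Of 36 genes of autophagy and lysosome 5 rose and 3 fell (5 and 3), with SQSTM1 at -1.10 (-0.71 set-adjusted) and a list p of 0.633. CYP7A1, the rate-limiting enzyme of bile acid synthesis, rose by 2.02 (adjusted p = 0.0430) and had -0.79 set-adjusted (adjusted p = 0.384).

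Cell type markers are read from whole tissue. Of 29 hepatocyte markers 1 rose and 1 fell (0 and 0 adjusted over the list alone), with AMBP at -0.71 (-0.77 set-adjusted), adjusted p of the list = 0.914. Set-adjusted, 24 of the 29 were lower and the list passed downward (median -0.36, adjusted p = 0.00130; adjusted p = 0.556 with an estimated correlation), with 1 member higher and 0 lower adjusted over the list alone. Of 30 T and NK cell markers CD3D fell (-0.96, and -0.21 set-adjusted), and 0 passed adjusted over the list alone, with a list p of 0.221. Of 16 B and plasma cell markers 0 passed either way, with BLK at -0.61 (-0.30 set-adjusted) and a list p of 0.846. Of 31 markers of macrophages and dendritic cells 3 rose and 4 fell (3 and 9 adjusted over the list alone), with C1QC at -1.28 (-0.43 set-adjusted, and without control 3 -0.85 and 0.0047) and a list p of 0.0988. CD163 rose from 2 reads in controls to 62 with metformin, 17 of them in metformin 1, 3 and 4, a ratio of 18.3 (interval 4.87 to 155). Of 27 endothelial markers 0 rose and 4 fell (0 and 4), with TIE1 at -0.86 (-0.50 set-adjusted) and a list p of 0.190. Of 44 markers of stellate cells, fibroblasts and matrix 5 rose and 0 fell (4 and 0), with LOXL2 at 4.35 (0.76 set-adjusted) and DCN at 1.87 (-0.037 set-adjusted) and a list p of 0.451. Of 18 erythroid markers 1 rose and 1 fell (1 and 1), with TFRC at 3.37 (0.43 set-adjusted, moved by single libraries as given above), H1F0 at -0.89 (-0.62 set-adjusted) and a list p of 0.633. Of 21 cholangiocyte markers 3 rose and 1 fell (4 and 2), with PROM1 at 2.82 (0.31 set-adjusted) and a list p of 0.846. Of 15 adipocyte markers 3 rose and 2 fell (4 and 2), with CIDEC at -1.45 (-0.71 set-adjusted) and PLIN1 at -1.43 (-0.71 set-adjusted) and a list p of 0.633. Of 7 markers of oviduct and intestine 1 rose and 2 fell (1 and 4), with LYZ at -1.52 (-0.78 set-adjusted) and a list p of 0.283. Exocrine pancreas had 2 tested markers and skeletal muscle 4, too few for the list test, with AMY1A at 0.62 (adjusted p = 0.114, and -0.34 set-adjusted) and ACTA1 at -1.54 (adjusted p = 0.139, and -1.62 set-adjusted). In 13 lists, gluconeogenesis and hepatocytes among them, the median, the mean and the test differed in sign.

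Set-adjusted, 11 lists passed at the preset correlation that did not pass over all libraries, 2 upward and 9 downward, and 10 of them also passed in the middle set alone, where 0 did with an estimated correlation (smallest adjusted p = 0.347). Beside the lists of fatty acid synthesis, fatty acid oxidation and hepatocytes, these were the circadian clock upward (median 0.21, adjusted p = 0.0177) and 7 lists downward. Interferon response (-0.20, adjusted p = 0.0105), antioxidant genes (-0.21, adjusted p = 0.0241) and xenobiotic metabolism (-0.17, adjusted p = 0.0425) had an adjusted p = 0.556 with an estimated correlation, as had the clock. Acute phase genes (-0.41, adjusted p = 0.00701) and immediate early genes (-0.55, adjusted p = 0.0293) had an adjusted p = 0.709 with it. Macrophages and dendritic cells (-0.41, adjusted p = 0.0399) and endothelial cells (-0.31, adjusted p = 0.0326) had an adjusted p = 0.785 with it. Xenobiotic metabolism was the list that did not pass in the middle set alone (adjusted p = 0.0541). The set-adjusted metformin term rests on the same libraries as the fit of the middle set. Passing in both fits is therefore not a separate check of these lists.

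The largest rises lay in metformin 6 to 10. LRP1_1 averaged 179 CPM there, 0.228 CPM in metformin 2 and 5, and 0 CPM in metformin 1, 3 and 4, against 0.00896 CPM in controls. BEST1 averaged 1741 CPM in metformin 6 to 10 and 1.89 CPM in metformin 1, 3 and 4, against 1.05 CPM in controls, and KIF28P 122 and 0.549 against 0.110 CPM. CLDN16L, CAMK1G, SLC18A1, PP2D1, PLEKHG7, SPATA22 and TCP11 were the other genes of this group. The largest falls held DIO3, which inactivates thyroid hormone, from 21.4 ± 26.7 to 0.806 ± 1.22 CPM, and ACACB from 3.75 ± 1.98 to 0.236 ± 0.259 CPM. ABCA12, SLC30A2, IFI6, CHAC1, CYP2C23b, AvBD6 and AVD followed. ABCA12 lay below all controls in 0 of 10 metformin libraries and AVD in 2 of 10. ABCA12 and SLC30A2 had log2 fold changes of -3.75 and -3.20, which were -2.40 and -1.90 without control 5, with adjusted p of 0.0736 and 0.186. The AVD difference rested on control 3, without which the log2 fold change was 0.42 (adjusted p = 0.602).

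Among 21 genes of yolk precursors and very low density lipoprotein secretion 3 rose and 2 fell (3 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.768). APOA4 fell by 1.97 and had -1.37 set-adjusted. ESR1, the oestrogen receptor, rose from 5.31 ± 1.26 to 15.4 ± 5.89 CPM, with 0.55 set-adjusted. MTTP, which loads lipid onto apolipoprotein B, had 3.22 (adjusted p = 0.0273) and 0.07 set-adjusted (adjusted p = 0.974). The vitellogenins VTG1 and VTG2 had log2 fold changes of 0.65 (adjusted p = 0.621) and 0.66 (adjusted p = 0.521), APOV1 -0.85 (adjusted p = 0.448) and APOB 1.02 (adjusted p = 0.116). Set-adjusted they had 0.0078, -0.40, -0.53 and 0.052, in the same order, so that VTG2 changed sign. Metformin 10 had 0.458 CPM of VTG1, 88.4 CPM of VTG2 and 1.93 CPM of APOV1. Without it the log2 fold changes were 0.86 for VTG1, 0.87 for VTG2 and -0.65 for APOV1, with adjusted p of 0.152, 0.137 and 0.0884.

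**Figure D3:**
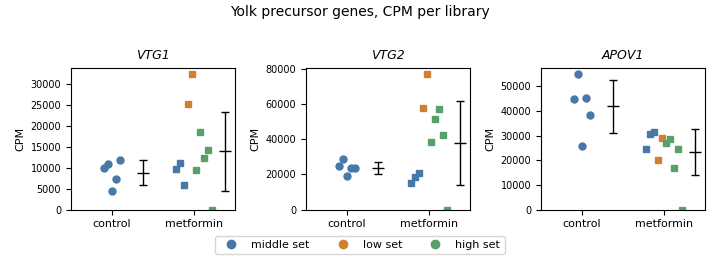
CPM (y axis) of VTG1, VTG2 and APOV1 with 1 point per library, colour for the library set, and mean and SD beside each group. Metformin 10 lies near 0 in all 3 panels, at 0.458, 88.4 and 1.93 CPM.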

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

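The tests of set differences, of gene length, of the hepatocyte markers in metformin 10, of splits within the middle set against the other 10 libraries, and of the genes called in splits of the middle set were chosen after the results were seen; the tests of depth, neighbours, the share of reads in no gene and the other splits were written down before, although matching by gene number and synonym was added to the neighbour test after its first value (an odds ratio of 5.3 by symbol alone). In each group, the gap between the highest or lowest library and its neighbour was set against the full range of the group, on log2 CPM for genes. For normally distributed values chance sets a library apart in about 1 in 20 groups, a rough guide here because the metformin libraries fall into sets. A library was set apart in 29 of 372 groups. In 5 of the 29 the other controls had no read, so that 1 to 3 reads set the library apart, which says nothing about it: LRP1_1 (1 read, 0.0448 CPM) and CLDN16L (2 reads, 0.0896 CPM) in control 3, SLC19A2 (1 read, 0.0420 CPM) and ALDH1L2 (3 reads, 0.126 CPM) in control 4, and CD163 (2 reads, 0.0940 CPM) in control 5.

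Metformin 10 stood low in VTG1 (0.458 CPM, against 5967 to 32409 CPM in the other metformin libraries), VTG2 (88.4 CPM, against 15321 to 76778), APOV1 (1.93 CPM, against 17060 to 31361) and CYP4B7 (11.1 CPM), and high in C1QA (108 CPM). RBP, FABP1 and VTG3, chosen after their values were seen, were at 78.0, 12.4 and 1.93 CPM against means of 1454, 522 and 4384 CPM in metformin 6 to 9. A library from another tissue or with few hepatocytes is argued against: the median log2 ratio of metformin 10 to metformin 6 to 9 over 28 hepatocyte markers without APOB was 0.50, with quartiles of -0.20 and 0.68. ESR1 was at 17.7 CPM, within the 14.9 to 22.0 CPM of metformin 6 to 9. A hen out of lay may account for these values, which stays open, since the labels give no laying record and no biological explanation was tested.

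The mean share of reads in no gene was 52.7% in metformin 6 to 10, above the 27.8% to 36.3% of the controls, in reads outside the gene counts. Counting of reads of the opposite strand in these libraries was checked as an explanation of the split into sets. Genes over 8-fold higher there than in metformin 1, 3 and 4 overlapped a gene among the highest 10% by expression with an odds ratio of 5.43 (Fisher's exact test, 95% interval 3.80 to 7.61). Of these 468 genes only 65.8% had a place in the reference table, so the check is void and the explanation stays open. Between metformin 2 and 5 and metformin 1, 3 and 4, the log2 ratio rose with gene span at a Spearman rho of 0.41 across genes, which are not independent replicates, and 0.34 to 0.42 in single library pairs. This is consistent with a length bias between these sets, and no biological explanation of the sets was tested.

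For the genes called over all libraries, lower depth of metformin 6 to 10 is argued against, since 2237 genes were called with every library thinned to the smallest gene total, against 2632. Set differences with no metformin effect stay open. Simulations of them gave 0 to 1 set-adjusted calls against 5, but they drew each gene independently, without variation that a library shares across genes. In the middle set another split of the real libraries called 11 genes, so the simulated calls do not decide it. The median ratio of the set-adjusted to the all-library log2 fold change was 0.20 (jackknife SE 0.12) for the genes called higher and 0.48 (jackknife SE 0.11) for those called lower. Within the middle set, library quality may also contribute: the slope on the share in no gene within the controls correlated with the metformin difference at r = 0.11 across genes, -0.015 to 0.16 with 1 control left out, which does not decide it. Metformin as the cause of the differences in the middle set stays open as well.

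Other splits of the same libraries were counted, the real one included; the 100 splits of all libraries held that of metformin 6 to 10 against the rest by choice, and the others were drawn at random. As many genes were higher in 4 of 100 splits and as many were lower in 3 of 100, so groupings drawn at random over all libraries rarely gave as many. This does not separate metformin from the library sets: 93 of the 98 drawn splits called 0 genes. The highest other values were 2087 and 1805, against 1805 and 827, both from the split of metformin 6 to 10 against the rest, which points to a structure of the samples. Where the 5 libraries taken as controls came from the middle set, which leaves the low and high sets in the other arm, 10 of 56 splits gave as many higher (highest other 2467) and 9 of 56 as many lower (highest other 1653). Chance is therefore not excluded for either count once the sets are held in place. For gene lists 37 of 100 splits gave at least 9, the highest other being 18, so chance is not excluded. In the middle set 2 of 56 splits gave as many genes at an unadjusted p under 0.05 (1390, highest other 1408). For lists at the preset correlation 1 of 56 gave as many (18, highest other 17). Few of the 56 splits reached these 2 counts, but the highest other values lay close, so chance is made less likely and is not excluded. With an estimated correlation 0 lists passed there (smallest adjusted p 0.347). At the adjusted threshold the real split called 1 gene, 8 of 56 splits called as many and the highest other called 11, so chance is not excluded for the calls.

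Single libraries apart from their group in the remaining genes were as follows. Control 3 was high in AVD (50.1 CPM), HELZ2 (7.48 CPM) and C1QC (412 CPM), and low in APOB (3776 CPM). Control 4 was high in IFI6 (103 CPM), PGK1 (94.4 CPM) and PFKFB3 (52.5 CPM), and low in ACO1 (107 CPM) and LYZ (2.52 CPM). Control 1 was low in MPC1 (77.9 CPM) and high in NARS (10.7 CPM), and control 2 was high in GART (204 CPM) and DUSP1 (265 CPM). Control 5 was high in ATF6 (44.6 CPM) and low in CEBPA (40.7 CPM). Metformin 3 was low in ACAA2 (25.7 CPM), SLC22A4 (0 CPM), CHDH (7.72 CPM) and HSPA4L (3.76 CPM).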

How the results depend on the processing

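The fits with the library set and of the middle set alone were chosen after seeing the data. Over all libraries 1805 genes were higher, 827 lower and 9 lists passed. Counts stayed within 1.5 times with RLE or upper quartile factors, no filter, the stricter filter and robust dispersion. DESeq2 gave 3125 genes higher, and limma voom with quality weights 3323 higher and 4001 lower. With 1 surrogate variable 0 were higher and 0 lower, with the library set as a covariate 4 and 1, and in the middle set 0 and 1 by edgeR, where 1390 genes had an unadjusted p under 0.05. Lists past the threshold numbered 0 with an estimated correlation, 19 with the library set and 18 in the middle set, and with an estimated correlation 0 in both (smallest adjusted p 0.123 and 0.347). The surrogate variable followed the library sets. It was -0.275 to -0.201 in the middle set, 0.0014 and 0.0116 in the low set, and 0.320 to 0.373 in the high set. It therefore largely repeated the adjustment for the set. The cause of the other shifts was not tested.

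With the replicate block 0 genes were higher and 0 lower. Same-numbered libraries did not deviate together: the correlations of their deviations were -0.04 to 0.069 over 5 pairs, and 1 of 5 controls correlated best with its own number. No pairing was seen, but the deviations of the metformin libraries held the set differences, which could hide a pairing. Metformin 6 to 10 have no partner in the block. BEST1 (-0.36) and LCT (-0.36) changed sign under the block.

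Leaving out 1 library gave 0 to 3011 genes higher, 0 to 2293 lower and 8 to 12 lists. Counts higher moved by over 1.5 times without each of the controls (540, 2, 233, 16 and 0 without controls 1 to 5) and without metformin 3 (3011), 7 (971), 8 (870), 9 (1176) or 10 (1175). Counts lower moved whichever library was left out: 336, 4, 182, 39 and 0 without controls 1 to 5, and 1266, 515, 2293, 1556, 505, 448, 329, 294, 425 and 459 without metformin 1 to 10. Of the 186 named genes, 178 had a value in every such fit, 173 in the middle set and 185 with the stricter filter, and 0 kept a call in every leave-out. The last count was fixed by the 0 genes called without control 5. Log2 fold changes of 8 called named genes moved by over 1.5 times without 1 control: ABCA12, SLC30A2, IFI6, AVD, C1QC, LBP (-0.48 without control 3), BTG2 (-0.64 without control 2) and C1QA (-0.43 without control 3). Set-adjusted, a leave-out chosen after seeing the data, 16 named genes passed without control 1, 3 of them without control 4, and ANGPTL4 without metformin 3 or 10. Set-adjusted log2 fold changes also moved without 1 library, and such moves are given above for some genes only. AVD changed sign without control 3 (0.42) and ranged from there to -2.95 with another library left out.

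Of 172 named genes called, 152 kept their sign with the library set but were no longer past the threshold, 16 changed sign and 4 had no value. With 1 surrogate variable the log2 fold change was -1.96 for LRP1_1, -0.90 for CLDN16L, -4.01 for SLC18A1, -3.80 for PP2D1, -2.63 for PLEKHG7, -4.30 for SPATA22, -0.091 for PCCA and -0.92 for LCT. With the library set it was -1.28 for LRP1_1, -1.28 for SLC19A2, -0.0027 for AQP9, and, with the value in the middle set alone second, -0.17 and -0.14 for PGK1, -0.54 and -0.52 for AKT1, -0.51 and -0.53 for EDEM1, -0.79 and -0.78 for CYP7A1, -0.028 and -0.011 for ADSSL1, -0.083 and -0.063 for GART, -0.14 and -0.12 for ALDH4A1, -0.13 and -0.11 for PCCA, -0.25 and -0.23 for HSP90AA1, -0.36 and -0.34 for HSPD1, -0.24 and -0.22 for GHR, -0.037 for DCN (-0.013 second), and -0.25 and -0.27 for LCT. SLC18A1, PP2D1, PLEKHG7 and SPATA22 had no count in the middle set, so the set-adjusted fit gives them no value. For the same reason their negative values with 1 surrogate variable do not show a reversal. No gene passed the threshold in the fit with 1 surrogate variable.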

Other observations

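With the library set as a covariate 5 genes passed in edgeR, all chosen here after their values were seen. C2H8ORF22 was lower (-2.40, adjusted p = 0.00375), and RBBP6 (1.22, adjusted p = 0.0252), IL20 (1.71, adjusted p = 0.0436), LOC112530328 (4.34, adjusted p = 0.0252) and EYY68_mgt22 (1.77, adjusted p = 0.0239) were higher. Over all libraries C2H8ORF22 had the opposite sign, 0.84 (adjusted p = 0.338).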
